A study of Mus musculus with 8 samples.

How the data were processed

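RNA was measured in 8 pools of sorted mouse yolk sac cells from stage E11.5, 25 cells per pool in 6 libraries and 24 in the other 2. Per the labels, polyadenylated RNA was copied and amplified by the Smart-seq2 protocol with 14 cycles of PCR, a method that reads full-length transcripts and carries no molecular identifiers. The deposited table held raw read counts per gene symbol, with no scaling between libraries, for 24454 gene rows. The submitters' processing notes name FastQC for read quality, HTSeq for counting and mm10 as the genome build. Their versions, the aligner, the annotation and the strand setting are not given in the sources used here. Every value column was matched to a sample by its title, and 23337 gene rows matched a RefSeq symbol. Gene positions were taken from the GENCODE annotation of GRCm38. The raw sequence reads were not used here.

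The libraries were grouped by their sorting gates into endothelial (3 libraries), erythroid (3) and double positive (2). Total counts per library ran from 3723128 to 7618444, and 3 counts over a group were taken as the floor where a group had 0 counts. A fold against a group at 0 was computed against that floor and written as at least that fold. A fold against a group with 1 to 3 counts was given with a 95% counting interval. Replicate pairs were checked for copies, and none was identical. The comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where stated.

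Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 12136 genes. Library sizes were scaled by trimmed mean of M values (TMM) factors, and normalised read counts (CPM) use these effective sizes, so they are not shares of a library's counts. A quasi-likelihood model with 1 mean per population was fitted to all 8 libraries with robust estimation, and the 3 populations were compared in pairs. The common biological coefficient of variation was 0.5413. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. A gene counted as above or below both populations when both comparisons of the double positive libraries passed in the same direction.

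The 25 gene lists held 445 members, of which 429 were in the table, 3 of them under an older symbol. They were core endothelial, arterial, venous and Lyve1-type sinusoidal, hemogenic and progenitor, pan-hematopoietic, erythroid transcription factors, heme synthesis, embryonic globins, adult globins, erythroid membrane and surface, iron handling, terminal erythroid maturation, macrophage, megakaryocyte and platelet, granulocyte and mast cell, visceral endoderm, mesenchyme and mesothelium, basement membrane and matrix, BMP and TGF-beta response, S phase, G2 and M phase, glycolysis, immediate early and stress, mitochondrially encoded, and ribosomal protein genes. Of these, 22 lists were tested with camera at a preset correlation of 0.01, adjusted over 66 tests, and again with camera at an estimated correlation and with fry. Counts of members past the test are given over all genes tested and adjusted over the list alone. Scores per library, the mean log2 CPM of a list, were compared by exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3 or 3 against 2 libraries.

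Genes were named by a fixed rule. Cdh5 came first because the cells were sorted on its protein. In each comparison came the 8 largest rises and the 8 largest falls among genes past the test with at least 50 CPM in the higher population and no overlap of libraries. In each list came up to 4 members with the smallest adjusted p, and for genes above or below both populations the 10 with the largest smaller-of-both change under the same limits. Runx1, Gfi1, Gfi1b, Kit, Gata1, Klf1, Tfrc, Slc40a1, Alas2, Hbb-y, Hbb-bh1, Hba-x, Pecam1, Kdr, Ptprc and Afp were read whatever their values. Of the genes this rule names, 1 is not reported here. Kdr stood at 286 ± 104, 0 and 40.2 ± 13.4 CPM in endothelial, erythroid and double positive libraries.

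The fit was tested on simulated data with known changes in 50 genes at each fold and the dispersions of these libraries. At a 4-fold change it recovered 32% of changed genes for erythroid against endothelial, 24% for double positive against endothelial and 30% for double positive against erythroid libraries, and at 16-fold 64%, 56% and 58%. Of 11936 unchanged genes it called 6, 3 and 4. The real comparisons called many more genes than were changed here, which makes their adjusted threshold less strict. The recovery rates therefore do not carry over to them. Alternatives were DESeq2, limma-voom, relative log expression (RLE) factors, library size alone, globin genes removed before library sizes, no filter on low counts, a filter at a minimum count of 50, only the populations compared, a test against a fold of 1.5, thinning to the smallest library, and leaving out each replicate in turn. Removing Rn45s before library sizes was an alternative chosen after seeing the data.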

Results

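The data were gene-level read counts from 8 pools of cells sorted from mouse yolk sac at stage E11.5, the extraembryonic tissue that holds the first blood cells and vessels. The embryos were C57BL/6 and carried a green fluorescent protein (GFP) reporter on 1 allele at the locus of the erythroid microRNAs miR-144 and miR-451. Cells were sorted by an antibody to VE-Cadherin, the endothelial adhesion protein encoded by Cdh5, and by GFP. There were 3 pools of 25 VE-Cadherin positive, GFP negative cells (endothelial, replicates 1 to 3) and 3 pools of 25 VE-Cadherin negative, GFP positive cells (erythroid, replicates 4 to 6). A further 2 pools of 24 cells were positive for both (double positive, replicates 7 and 8). Total counts ran from 3723128 to 4439165 in the endothelial libraries, from 5291843 to 7618444 in the erythroid libraries, and were 4637930 and 4818074 in the double positive libraries. Genes with at least 1 count numbered 11744 to 11884 in endothelial, 8673 to 8746 in erythroid, and 14059 and 13980 in double positive libraries. Globin genes took 54.5% to 56.5% of all counts in the erythroid libraries, 8.86% and 14.0% in the double positive libraries, and 0.0022% to 0.004% in the endothelial libraries. Rn45s, a ribosomal RNA precursor, took 18.1% to 21.3% of endothelial, 11.6% to 12.9% of erythroid, and 11.9% and 13.0% of double positive counts. The first principal component of log2 CPM held 59.8% of the variance and the second 23.4%, and the 3 populations lay apart on them. Whether pools came from separate embryos is not stated in the labels, so the p-values measure only the spread between these pools, which may be technical. The reads carried no molecular identifiers, so intervals and floors cover counting error only.

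Cdh5, which encodes the sorted surface protein, was read first, and the table has no GFP row. Cdh5 (chromosome 8, 104101625 to 104144511, plus strand, GRCm38) stood at 209 ± 32.0 CPM in the endothelial libraries (SD, n = 3), at 0 in all 3 erythroid libraries, and at 51.0 ± 7.19 CPM in the double positive libraries (SD, n = 2). Its level in the double positive libraries was 4.09-fold lower than in the endothelial libraries (log2 difference −2.03, SE 0.25, adjusted p = 0.00201 by edgeR's quasi-likelihood test) and at least 178-fold higher than in the erythroid libraries. Counts at the annotated Mir144 (chromosome 11, 78073005 to 78073070, plus strand), chosen after its values were seen, stood at 338 ± 3.23 CPM in erythroid, 25.3 ± 4.63 CPM in double positive and 0.437 ± 0.194 CPM in endothelial libraries. Mir451a had 0 counts in every library. The 3 embryonic globins present in the table were ordered the same way. Hbb-y, the embryonic beta-type chain, stood at 550110 ± 16499 normalised CPM in erythroid (SD, n = 3), 64971 ± 24973 in double positive (SD, n = 2) and 11.9 ± 3.36 in endothelial libraries (SD, n = 3). Hbb-bh1 and Hba-x were 10.2-fold and 9.83-fold lower in double positive than in erythroid libraries. The 6 adult globin rows held 0 counts in total in all 8 libraries. These genes are near-identical copies, whose reads a counting step can discard, so their level is uncertain. None of the 13 mitochondrially encoded genes listed was in the table.

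The comparison of the erythroid with the endothelial libraries sets the VE-Cadherin negative, GFP positive pools against the VE-Cadherin positive, GFP negative pools. The endothelial pools also held macrophage transcripts, that list summing to 1127, 3410 and 1086 CPM in replicates 1, 2 and 3. Genes lower in erythroid libraries therefore cannot all be assigned to vessel cells. Erythroid libraries were higher for the transcripts of hemoglobin and heme production, of the red cell membrane and of the erythroid transcription factors, and lower for every member of the endothelial list. Klf1, an erythroid transcription factor, stood at 764 ± 13.9 CPM in the erythroid libraries and at 0 in the endothelial libraries, at least 5062-fold higher (adjusted p = 4.11e-07, n = 3 and 3, edgeR). Lyve1, a hyaluronan receptor of yolk sac and lymphatic endothelium, stood at 999 ± 72.9 CPM in the endothelial and at 0 in the erythroid libraries, at least 3499-fold lower in the latter. Of 12136 genes tested, 1745 were higher and 3232 lower in erythroid than in endothelial libraries, and 1943 of the called genes had 0 counts in the lower population. The libraries did not overlap for 50.8% of the tested genes, against 10% by chance. Among the 8 largest rises, Hemgn, a nuclear protein of blood cells, was at least 16480-fold higher, and Rhag, of the Rh complex, at least 5919-fold. Slc4a1, the red cell anion exchanger, had 1 endothelial count and was 45100-fold higher, with a 95% counting interval of 8094 to 1781000. The 8 largest falls included the imprinted gene Mest (at least 10530-fold), the matrix protein gene Sparc (at least 4179-fold), the endothelial diaphragm protein gene Plvap (at least 3621-fold) and Col4a1, a basement membrane collagen (at least 2210-fold). They also held Lyve1, Anxa2, Mrc1 and Pf4.

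**Figure D1:**
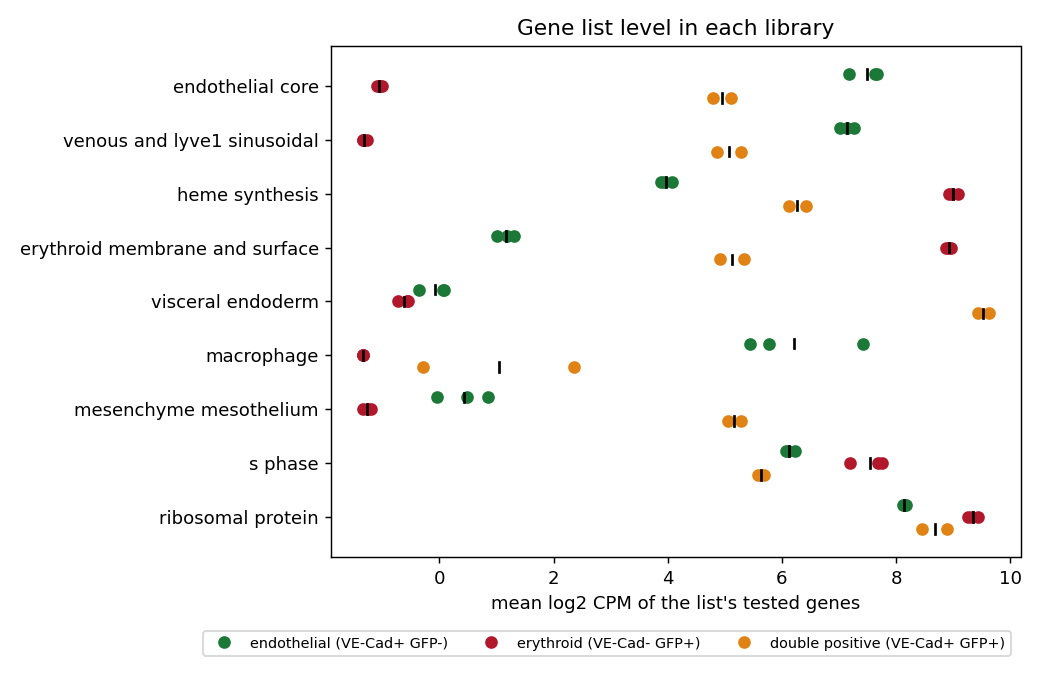
Mean log2 CPM of the tested genes of 9 gene lists (horizontal axis) in each of the 8 libraries, 1 point per library, with black bars at the population means. Visceral endoderm genes sit at 9.63 and 9.43 in the double positive libraries and at 0.0882 or lower in the other 6; for ribosomal protein genes the order of erythroid and endothelial libraries turns under scaling by library size alone.

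The endothelial groups fell together in the erythroid libraries. All 35 core endothelial genes were lower (35 also adjusted over the list alone), with a median log2 difference of −12.88, or −9.45 with the 30 genes at 0 set to their bound. The list stood apart from other genes by camera (adjusted p = 8.84e-21) but not past the threshold with its own correlation (adjusted p = 0.0849 with an estimated correlation). Of 12 arterial genes 10 fell (12 adjusted over the list alone), among them the receptors Nrp1 and Notch1 (camera adjusted p = 2.14e-05; adjusted p = 0.282 with an estimated correlation). Of 12 venous and Lyve1-type sinusoidal genes 11 fell (12 adjusted over the list alone), including the scavenger receptor gene Stab2 (camera adjusted p = 7.94e-09, and 0.0346 with an estimated correlation). All 16 basement membrane and matrix genes fell (16 adjusted over the list alone, camera adjusted p = 1.53e-09; adjusted p = 0.0518 with an estimated correlation). Of 13 BMP and TGF-beta response genes 12 fell (12 adjusted over the list alone, camera adjusted p = 5.47e-06, and 0.0432 with an estimated correlation), led by the endothelial receptor gene Acvrl1. Immediate early and stress genes fell in 12 of 15 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.00192; adjusted p = 0.131 with an estimated correlation). Fos, an early response factor, stood at 12.7 ± 8.59 CPM in erythroid against 354 ± 132 CPM in endothelial libraries.

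Erythroid groups moved the other way. All 23 tested membrane and surface genes rose (23 adjusted over the list alone), with a median log2 difference of 10.16, or 9.68 with 9 genes at their bound (camera adjusted p = 1.59e-21, and 0.0365 with an estimated correlation). Heme synthesis genes rose in 14 of 15 cases (15 adjusted over the list alone, median log2 difference 4.79; camera adjusted p = 3.35e-13, and 0.0346 with an estimated correlation). Alas2, the first enzyme of erythroid heme synthesis, stood at 4692 ± 34.6 CPM against 1.08 ± 1.13 CPM. The 3 embryonic globins rose (3 adjusted over the list alone, camera adjusted p = 1.73e-05; adjusted p = 0.0849 with an estimated correlation), but their single-gene calls did not pass with limma-voom. Of 14 erythroid transcription factor genes 9 rose, among them Gata1 and Klf1, and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 7.29e-06, and 0.0347 with an estimated correlation). In the terminal maturation list 7 of 14 genes rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 5.25e-05, and 0.0384 with an estimated correlation), with a median log2 difference of 1.43 that was −0.12 under library size alone, where 4 were higher and 3 lower. Iron handling split, with 13 of 29 genes higher and 7 lower (14 and 10 adjusted over the list alone), against 10 higher and 14 lower under library size alone, with a median of −1.63. The transferrin receptor gene Tfrc rose from 38.0 ± 7.16 to 424 ± 50.5 CPM, and Hmox1, the heme-degrading enzyme gene, was lower by 1917-fold (95% counting interval 344 to 75730). The median log2 difference of the iron list was −0.08, its mean with genes at their bound 0.01, and camera placed it upward (adjusted p = 0.016; adjusted p = 0.312 with an estimated correlation).

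Cell cycle and ribosomal protein genes were higher in the erythroid libraries under the main scaling, but not under library size alone. S phase genes rose in 15 of 18 cases (15 adjusted over the list alone, camera adjusted p = 1.21e-07; adjusted p = 0.134 with an estimated correlation), and Mcm2, a replicative helicase subunit, stood at 423 ± 37.2 against 79.8 ± 13.7 CPM. G2 and M phase genes rose in 10 of 18 cases (12 adjusted over the list alone, camera adjusted p = 6.24e-06; adjusted p = 0.225 with an estimated correlation). Ribosomal protein genes, whose pseudogenes make their levels uncertain, rose in 39 of 41 cases (40 adjusted over the list alone, camera adjusted p = 4.39e-16; adjusted p = 0.225 with an estimated correlation). Under library size alone the median log2 differences of these 3 lists turned from 1.502 to −0.04, from 0.90 to −0.65 and from 1.19 to −0.36. There 2, 1 and 3 genes were higher and 2, 7 and 23 lower. Glycolysis genes rose in 2 and fell in 8 of 16 cases (2 and 10 adjusted over the list alone, camera adjusted p = 0.178), and Pkm, the pyruvate kinase gene, fell from 791 ± 6.79 to 47.8 ± 4.52 CPM. Scaling by library size alone, with globin taking over 54.5% of erythroid counts, moved the median log2 difference of all genes by −1.54 in this comparison, by −0.632 between double positive and endothelial libraries, and by 0.903 between double positive and erythroid libraries. With it, 420 genes were higher and 7270 lower, so the share of higher genes among those called went from 35.1% to 5.46%.

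Markers of other blood and tissue cells were read in the same libraries. Macrophage genes fell in 13 of 14 cases in erythroid against endothelial libraries (14 adjusted over the list alone, camera adjusted p = 2.4e-05; adjusted p = 0.287 with an estimated correlation), all 14 having 0 counts in the erythroid libraries. Their summed level was 1127, 3410 and 1086 CPM in endothelial replicates 1, 2 and 3. The macrophage list in replicate 2 had a median log2 excess of 1.61 over the other endothelial libraries, at percentile 100 of 10000 random lists matched on mean expression. For replicates 1 and 3 the medians were −0.653 and −0.814, both at percentile 0. Each of these was set against a mean that held replicate 2, so their low medians do not show a depletion of their own. The random lists were drawn gene by gene and lack the shared variation of macrophage genes, so the percentiles do not measure chance. Adgre1, a macrophage surface antigen gene, stood at 102 ± 39.99 CPM and Csf1r, the receptor for macrophage colony-stimulating factor, at 252 ± 208 CPM in the endothelial libraries. Pan-hematopoietic genes fell in 11 of 13 cases (13 adjusted over the list alone, camera adjusted p = 5.25e-05; adjusted p = 0.198 with an estimated correlation), Ptprc, the CD45 gene, from 42.4 ± 31.4 CPM to 0. Of 10 megakaryocyte and platelet genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.285), against 0 and 8 under library size alone, with Pf4 at 642 ± 230 CPM in endothelial and 0 in erythroid libraries. Of the granulocyte and mast cell list only Hdc was tested, at 1.92 ± 1.06, 0 and 4.36 ± 3.29 CPM in endothelial, erythroid and double positive libraries, and it was lower in erythroid libraries than in both others, against the double positive libraries not without replicate 7 or 8. Visceral endoderm genes were low in both populations, with summed levels of 48.7 and 22.0 CPM, and 1 of 25 fell in erythroid libraries, the retinol carrier gene Rbp4 (1 adjusted over the list alone). The median of that list was −0.26 while camera placed it upward without passing (adjusted p = 0.968), and 8 fell under library size alone. Mesenchyme and mesothelium genes fell in 3 of 9 cases (3 adjusted over the list alone, camera adjusted p = 0.209). Without replicate 2, 1612 genes were higher and 3035 lower in erythroid than in endothelial libraries.

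The double positive cells carried VE-Cadherin as the endothelial cells did and GFP in addition. Their libraries held embryonic globins, heme synthesis and red cell membrane transcripts far above the endothelial level. Endothelial transcripts were present at lower levels than in the endothelial libraries. Transcripts of visceral endoderm, the absorptive and secretory epithelium of the yolk sac, were abundant. Rhag stood at 59.0 ± 18.0 CPM in the double positive (SD, n = 2) and at 0 in the endothelial libraries (SD, n = 3), at least 391-fold higher (adjusted p = 2.09e-05, edgeR). Pecam1, the endothelial adhesion gene for CD31, was 8.69-fold lower, at 48.4 ± 5.96 against 421 ± 99.0 CPM. Afp, the alpha-fetoprotein gene of visceral endoderm and fetal liver, was 3393-fold higher, at 54340 ± 1590 against 16.1 ± 5.16 CPM. In all, 1776 genes were higher and 840 lower in double positive than in endothelial libraries, with no overlap of libraries for 57.5% of tested genes against 20% by chance. The 8 largest rises were the tight junction gene Cldn6 (at least 4958-fold), the endocytic receptor genes Lrp2 (at least 4142-fold) and Cubn (14720-fold, 95% counting interval 4075 to 121600), the plasma protein genes Serpina1b, Ambp, Serpind1 and Gc, and Timd2. Chemokine genes Ccl3 (at least 325-fold) and Ccl2 (686-fold, 95% counting interval 123 to 27090) led the 8 largest falls, which also held Adgre1, Fcrls, F13a1, Lst1, Dok2 and the myeloid transcription factor gene Spi1. Adgre1 belongs to the macrophage list, which summed to 1127, 3410 and 1086 CPM in endothelial replicates 1, 2 and 3. In double positive replicates 7 and 8 that list summed to 40.1 and 104 CPM. A pool does not show which cell held a transcript, so these 8 falls cannot be assigned to the endothelial cells. The call for Ccl2 ended without replicate 8, and that for Lst1 without replicate 7.

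Each erythroid list and the iron handling list had more genes higher than lower in double positive than in endothelial libraries. The transcription factor and terminal maturation lists did not pass with camera but passed upward with fry (adjusted p = 1.22e-06 and 3.29e-05). Membrane and surface genes rose in 19 of 23 cases and fell in 1, Gypc, named after its values were seen (19 and 1 adjusted over the list alone), with a median log2 difference of 5.93, or 5.40 with 9 genes at their bound (camera adjusted p = 2.29e-10; adjusted p = 0.0823 with an estimated correlation). Heme synthesis genes rose in 13 of 15 cases (13 adjusted over the list alone, median log2 difference 1.85; camera adjusted p = 8.26e-06; adjusted p = 0.0582 with an estimated correlation). All 3 embryonic globins rose (3 adjusted over the list alone, camera adjusted p = 7.7e-05; adjusted p = 0.11 with an estimated correlation), though not with limma-voom. Erythroid transcription factor genes rose in 4 of 14 cases and fell in 2 (6 and 3 adjusted over the list alone, camera adjusted p = 0.336), with Klf1 at 28.8 ± 4.51 CPM and Gata1 at 14.0 ± 1.19 CPM against 0 for both in the endothelial libraries. In the terminal maturation list 5 of 14 genes rose (5 adjusted over the list alone, camera adjusted p = 0.0812), and its median log2 difference of 0.57 was −0.06 under library size alone, where 1 was higher. Iron handling genes rose in 13 of 29 cases and fell in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0336; adjusted p = 0.369 with an estimated correlation), against 8 and 3 under library size alone. Trf, the transferrin gene, rose from 60.2 ± 47.2 to 9824 ± 1818 CPM, where the whole iron list summed to 17610 CPM. Trf was also among the 8 largest rises over the erythroid libraries, so erythroid RNA alone does not account for its level. Ribosomal protein genes rose in 25 of 41 cases (33 adjusted over the list alone, camera adjusted p = 0.000271; adjusted p = 0.518 with an estimated correlation), with a median log2 difference of 0.58 that was −0.07 under library size alone. There 0 were higher and 2 lower, and 12 were higher with RLE factors.

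Endothelial groups were lower in double positive than in endothelial libraries. Core endothelial genes fell in 30 of 35 cases (33 adjusted over the list alone), with a median log2 difference of −2.63 (camera adjusted p = 1.92e-20; adjusted p = 0.0849 with an estimated correlation). Arterial genes fell in 6 of 12 cases (7 adjusted over the list alone, camera adjusted p = 3.74e-05; adjusted p = 0.287 with an estimated correlation), and venous and sinusoidal genes in 9 of 12 (9 adjusted over the list alone, camera adjusted p = 3.85e-07, and 0.0347 with an estimated correlation). Lyve1 was 14.3-fold and Stab2 4.92-fold lower. Basement membrane and matrix genes fell in 8 of 16 cases (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000293; adjusted p = 0.155 with an estimated correlation). Of 13 BMP and TGF-beta response genes 3 fell and 1 rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.0393; adjusted p = 0.201 with an estimated correlation). Id2, an inhibitor of differentiation factors, rose from 63.7 ± 4.60 to 354 ± 44.3 CPM, a call that ended without replicate 8, while Acvrl1 fell 12.5-fold. S phase genes fell in 4 of 18 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.011; adjusted p = 0.397 with an estimated correlation), with Mcm3 2.78-fold lower, a call that ended without replicate 7. Under library size alone 13 S phase genes were lower and 0 higher, with a median of −1.22 against −0.59, and with DESeq2 7 were lower and 1 higher. In the G2 and M phase list 1 of 18 genes passed, Birc5, and 0 passed adjusted over the list alone (camera adjusted p = 0.12). In that list 0 were higher and 7 lower with DESeq2, 4 lower with RLE factors and 8 lower under library size alone. Birc5 stood 1.55-fold higher, and its call did not hold in 11 of the settings tried, in 1 of which, library size alone, its sign turned. Glycolysis genes rose in 2 and fell in 2 of 16 cases (3 and 2 adjusted over the list alone, camera adjusted p = 0.968), with a median log2 difference of 0.24 that was −0.38 under library size alone. Of 15 immediate early and stress genes 2 fell (1 adjusted over the list alone, camera adjusted p = 0.0149; adjusted p = 0.198 with an estimated correlation), Hspa1a by 7.39-fold, though Hspa1a and Hspa1b are near-identical copies and their levels are uncertain.

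Markers of other cells moved in both directions in this comparison. All 25 visceral endoderm genes rose (25 adjusted over the list alone), with a median log2 difference of 10.94, or 10.64 with 9 genes at their bound (camera adjusted p = 2.3e-21, and 0.0346 with an estimated correlation). Mesenchyme and mesothelium genes rose in 7 of 9 cases (8 adjusted over the list alone, camera adjusted p = 4.66e-05, and 0.0384 with an estimated correlation), and Col1a2, a fibrillar collagen, stood at 76.8 ± 4.61 against 2.85 ± 1.84 CPM. Macrophage genes fell in 11 of 14 cases (13 adjusted over the list alone, camera adjusted p = 1.06e-07; adjusted p = 0.198 with an estimated correlation), their summed level being 40.1 and 104 CPM in the double positive replicates 7 and 8. Pan-hematopoietic genes fell in 9 of 13 cases (11 adjusted over the list alone, camera adjusted p = 2.28e-07; adjusted p = 0.128 with an estimated correlation). Megakaryocyte and platelet genes fell in 3 of 10 cases (3 adjusted over the list alone, camera adjusted p = 0.126), and the call for Pf4, at 24.4 ± 33.2 CPM, ended without replicate 1, 2 or 3. The count of 840 lower genes was 1415 with DESeq2, 1422 with only these populations in the fit, 544 against a fold of 1.5, 502 without replicate 1 and 549 without replicate 3. Without replicate 7 or 8, which leaves 1 double positive library, 838 or 696 genes were higher and 219 or 281 lower. Under library size alone 1118 were higher and 1901 lower, 37.0% higher against 67.9%.

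Against the erythroid libraries, the double positive libraries had more of the endothelial and visceral endoderm transcripts and less of the erythroid ones. Embryonic globins were from 8.47-fold (Hbb-y) to 10.2-fold (Hbb-bh1) lower. Among other erythroid genes, Slc4a1 was 29.7-fold lower (76.2 ± 11.54 against 2267 ± 94.4 CPM), Klf1 26.5-fold, Alas2 20.8-fold and Gata1 20.5-fold (adjusted p = 4.65e-06 to 0.000261, n = 2 and 3, edgeR). Some fell less than the globins, with Cpox at 22.0% and Prdx2 at 17.5% of their erythroid level, against 11.8% for Hbb-y. The median log2 differences were −3.30 for globins, −3.28 for transcription factor, −3.10 for heme synthesis and −3.92 for membrane and surface genes. Core endothelial genes all rose. In all, 3820 genes were higher and 1283 lower, 2170 of the called genes having 0 counts in the lower population, and the libraries did not overlap for 67.5% of tested genes against 20% by chance. The largest rises were in Spp2 (at least 14590-fold), the selenium peroxidase gene Gpx3 (at least 10930-fold), the apolipoprotein gene Apoa4 (at least 8434-fold), Cd63 (at least 3983-fold), Spink1 (at least 3966-fold), the keratin gene Krt18 (at least 3428-fold), Tmem37 (at least 2849-fold) and Trf. The 8 largest falls were in the transferrin receptor gene Tfr2 (112-fold), Art4 (58.8-fold), Samd14 (58.8-fold), Chst10 (55.1-fold), the erythroid ubiquitin ligase gene Trim10 (44.7-fold), the urea transporter gene Slc14a1 (41.5-fold), the membrane skeleton gene Dmtn (40.4-fold) and the glycine transporter gene Slc6a9 (36.8-fold).

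**Figure D2:**
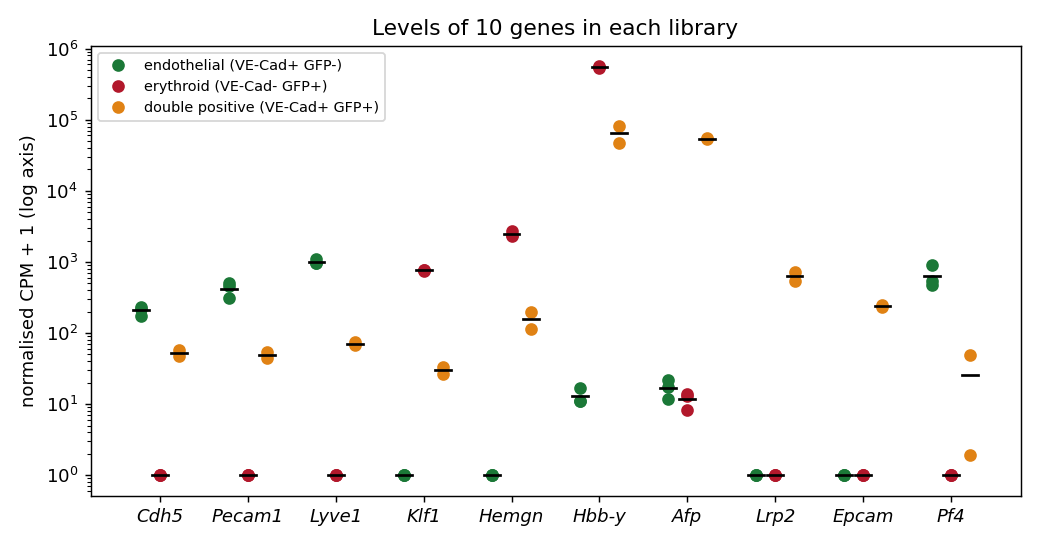
CPM of single genes in each of the 8 libraries on a log axis, 1 point per library, with black bars at the population means. Cdh5 stands at 209 CPM in endothelial, 51.0 in double positive and 0 in erythroid libraries, and Afp at 54340 CPM in the double positive libraries.

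Of the erythroid groups, membrane and surface genes fell in 21 of 23 cases (21 adjusted over the list alone, median log2 difference −3.92; camera adjusted p = 1.92e-18, and 0.0416 with an estimated correlation). Heme synthesis genes fell in 13 of 15 (14 adjusted over the list alone, median −3.10; camera adjusted p = 3.44e-11, and 0.0346 with an estimated correlation), and embryonic globins in 3 of 3 (3 adjusted over the list alone, camera adjusted p = 0.00102; adjusted p = 0.156 with an estimated correlation). With limma-voom, the falls of Hbb-y and Hba-x did not pass. Erythroid transcription factor genes fell in 9 of 14 cases (10 adjusted over the list alone, median −3.28; camera adjusted p = 4.71e-07, and 0.0346 with an estimated correlation). Terminal maturation genes fell in 6 of 14 cases and rose in 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.00038, and 0.0469 with an estimated correlation). Their median was −1.19, and under library size alone −0.27, with 4 lower and 2 higher. Iron handling genes rose in 10 and fell in 13 of 29 cases (12 and 13 adjusted over the list alone). The median of the iron list was −0.08 and its mean with genes at their bound 0.96, camera placed it downward (adjusted p = 0.0349; adjusted p = 0.369 with an estimated correlation), and its median was 0.85 under library size alone. S phase genes fell in 16 of 18 cases (16 adjusted over the list alone, camera adjusted p = 8.4e-11; adjusted p = 0.0849 with an estimated correlation) and G2 and M phase genes in 14 of 18 (15 adjusted over the list alone, camera adjusted p = 3.11e-08; adjusted p = 0.164 with an estimated correlation), with Mki67, the proliferation marker gene, at 112 ± 6.32 against 656 ± 48.6 CPM. Under library size alone 2 of the G2 and M phase genes were higher and 4 lower, with a median of −0.45 against −1.36. Ribosomal protein genes fell in 29 of 41 cases (29 adjusted over the list alone, camera adjusted p = 5.47e-11; adjusted p = 0.311 with an estimated correlation), with a median of −0.70 that was 0.20 under library size alone, where 13 were higher and 3 lower.

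Endothelial groups were higher in double positive than in erythroid libraries. All 35 core genes rose (35 adjusted over the list alone), with a median log2 difference of 10.31, or 6.79 with 30 genes at their bound (camera adjusted p = 9.04e-15; adjusted p = 0.128 with an estimated correlation). Arterial genes rose in 8 of 12 cases (9 adjusted over the list alone, camera adjusted p = 0.00329; adjusted p = 0.411 with an estimated correlation) and venous and sinusoidal genes in 11 of 12 (12 adjusted over the list alone, camera adjusted p = 5.65e-07, and 0.0347 with an estimated correlation). Basement membrane and matrix genes rose in 15 of 16 (15 adjusted over the list alone, camera adjusted p = 3.85e-07; adjusted p = 0.0797 with an estimated correlation), and BMP and TGF-beta response genes in 11 of 13 (11 adjusted over the list alone, camera adjusted p = 0.000354; adjusted p = 0.0785 with an estimated correlation). Glycolysis genes rose in 10 of 16 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.246), with Ldha, a lactate dehydrogenase subunit, at 1496 ± 472 against 247 ± 28.2 CPM. Immediate early and stress genes rose in 9 of 15 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.219). All 25 visceral endoderm genes rose (25 adjusted over the list alone, median 12.60, or 11.10 with 13 genes at their bound; camera adjusted p = 4.03e-13, and 0.0346 with an estimated correlation), as did all 9 mesenchyme and mesothelium genes (9 adjusted over the list alone, camera adjusted p = 0.000294, and 0.0469 with an estimated correlation). Macrophage genes rose in 3 of 14 cases (3 adjusted over the list alone, camera adjusted p = 0.296), against 8 with DESeq2 and 8 under library size alone. In the same comparison pan-hematopoietic genes rose in 4 of 13 and fell in 1 (4 and 1 adjusted over the list alone, camera adjusted p = 0.497). Of 10 megakaryocyte and platelet genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 5.56 against a downward placement by camera (adjusted p = 0.957). Without replicate 7 or 8, 2315 or 2401 genes were higher and 609 or 674 lower. Under library size alone 5760 were higher and 473 lower, 92.4% higher against 74.9%.

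The double positive libraries also differed from both other populations at once. A total of 1132 genes were higher in them than in both, and all 25 tested visceral endoderm genes were among these. These genes summed to 104100 CPM in the double positive libraries against 48.7 CPM in endothelial and 22.0 CPM in erythroid libraries, and to 11.8% and 10.6% of all raw counts in replicates 7 and 8. The 10 genes with the largest smaller-of-both change were Lrp2, Serpina1b, Ambp, Timd2, Serpind1, Gc, Cubn, the trefoil factor gene Tff3, 2610528J11Rik and the epithelial adhesion gene Epcam. Lrp2 stood at 625 ± 134 CPM (SD, n = 2) and had 0 counts in the other 6 libraries, so that it was at least 4142-fold above the endothelial and at least 2189-fold above the erythroid level. Of 9 mesenchyme and mesothelium genes 7 lay above both, as did 3 of 29 iron handling genes, 2 of 16 glycolysis genes, and 1 each of the terminal maturation and BMP and TGF-beta lists. Comparisons that share the double positive libraries share their chance values. Independent lists of these sizes would have 559 genes in common. The double positive libraries are too few to divide, so the part of the excess owed to sharing them was not measured. The count was 429 without replicate 7 and 413 without replicate 8.

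**Figure D3:**
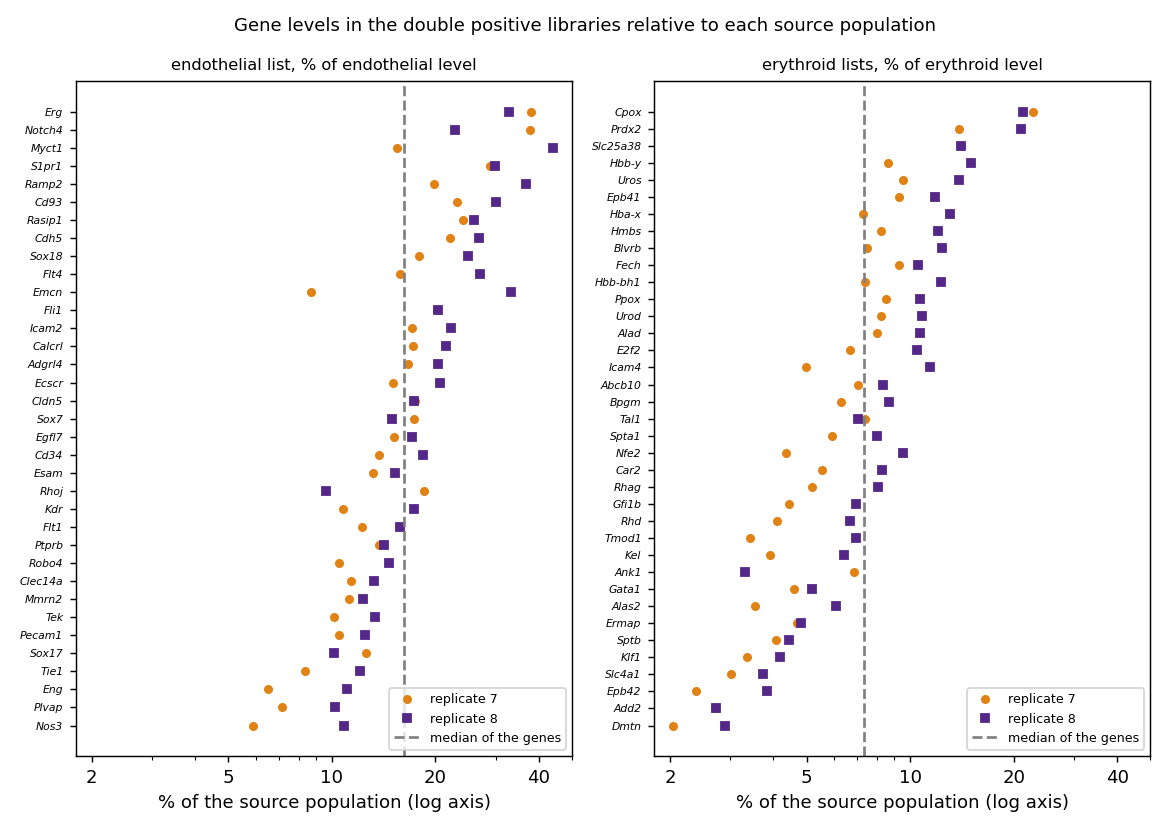
Levels in replicates 7 and 8 of the double positive population as a percentage of the mean endothelial level (left, 35 core endothelial genes) or erythroid level (right, 38 erythroid genes, 1 of them not drawn), on log axes, with dashed lines at the medians of 16.2% and 7.36%. Erythroid genes run from 2.47% (Dmtn) to 22.0% (Cpox), and endothelial genes from 8.38% (Nos3) to 35.4% (Erg), genes named after their values were seen.

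Below both other populations were 194 genes, where independent lists would share 88.8. The 10 with the largest change were D17H6S56E-5, the tubulin gene Tuba1a, the nucleoside transporter gene Slc29a1, the growth regulator gene Myc, the hematopoietic transcription factor gene Lyl1, Peli1, Tbl3, Mta2, Fam212a and Ewsr1. Lyl1 stood at 13.8 ± 3.00 CPM against 57.9 ± 13.7 in endothelial and 155 ± 19.5 in erythroid libraries, and Myc at 12.6 ± 1.82 against 55.8 ± 2.56 and 83.3 ± 23.6 CPM. Against the endothelial libraries, D17H6S56E-5 and Tuba1a lost their calls with limma-voom and without replicate 8, and Tbl3 without replicate 8. Below both lay 4 of 18 S phase, 0 of 18 G2 and M phase, 3 of 21 hemogenic and progenitor and 2 of 14 erythroid transcription factor genes. The count was 340 with DESeq2, 76 against a fold of 1.5, 43 without replicate 7 and 49 without replicate 8.

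Genes of hemogenic endothelium and early progenitors, from which blood cells arise in the vessel wall, were read as a list and singly. Runx1, the main regulator of this transition, stood at 4.86 ± 2.14 CPM in endothelial, 2.38 ± 2.15 in erythroid and 0.879 ± 0.379 in double positive libraries, with no difference past the threshold (adjusted p = 0.298 to 0.552, edgeR, n = 3, 3 and 2). Kit, the stem cell factor receptor gene, stood at 32.9 ± 24.3, 0 and 3.98 ± 1.58 CPM, and its difference between double positive and endothelial libraries was just short of the threshold (adjusted p = 0.0528) but passed with DESeq2, RLE factors and 6 other settings. Gfi1 was not tested, with 8 counts in endothelial replicate 1 and 0 elsewhere, and Myb had 0 counts in all libraries. Gfi1b, an erythroid and megakaryocyte factor gene of the same family as Gfi1, stood at 0.529 ± 0.916, 194 ± 37.2 and 11.0 ± 3.43 CPM. Of 21 tested genes of the list, 6 were higher and 12 lower in erythroid than in endothelial libraries (6 and 12 adjusted over the list alone, camera adjusted p = 0.344), against 3 and 13 under library size alone. Between double positive and endothelial libraries 1 was higher and 7 lower (2 and 11 adjusted over the list alone, median log2 difference −2.07; camera adjusted p = 0.000227; adjusted p = 0.0632 with an estimated correlation), against 1 and 11 with DESeq2. Between double positive and erythroid libraries 8 were higher and 7 lower (10 and 7 adjusted over the list alone). There the median was 3.71, or 0.10 with 9 genes at their bound, the mean at the bounds 0.60, and camera placed the list downward without passing (adjusted p = 0.339). The tested genes of this list shared 5 members with other lists. Its member Spi1 was also among the 8 largest falls in double positive against endothelial libraries, where macrophage genes fell too. Which cells carry that fall cannot be told from pools. The iron exporter gene Slc40a1 stood at 157 ± 52.6, 82.7 ± 15.4 and 148 ± 20.5 CPM in endothelial, erythroid and double positive libraries. Its fall in erythroid against endothelial libraries (1.90-fold, adjusted p = 0.0196, edgeR) ended against a fold of 1.5 and without replicate 2 or 5.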

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

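Removing Rn45s before library sizes was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the replicate numbers run from 1 to 8 without repeating across populations.

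The counts of genes in each comparison stayed within 1.5 times those reported with limma-voom, RLE factors, globin genes or Rn45s removed before library sizes, no filter on low counts, the stricter filter and thinning to the smallest library. With DESeq2, 1415 genes were lower in double positive than endothelial libraries and 340 below both populations. With only the populations compared, 1422 were lower in double positive than endothelial libraries, and against a fold of 1.5 there were 544, with 76 below both. For these 3 settings the cause was not tested. With library size alone, 420 genes were higher and 7270 lower in erythroid than endothelial, 1118 higher and 1901 lower in double positive than endothelial, and 5760 higher and 473 lower in double positive than erythroid libraries. That setting by construction leaves the globin share of erythroid counts uncorrected. How much of the change in each comparison is owed to globin was not tested.

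Leaving out in turn each replicate of the populations compared gave 1507 to 1612 genes higher and 2946 to 3158 lower in erythroid than endothelial libraries. It gave 696 to 1597 higher and 219 to 666 lower in double positive than endothelial, and 2315 to 3579 higher and 609 to 1143 lower in double positive than erythroid libraries. Above both populations were 413 to 1092 genes and below both 43 to 206. Without replicate 7 or 8 only 1 double positive library is left, which is assumed to vary like the other groups, so fewer libraries were tested. For the falls to 502 and 549 genes lower in double positive than endothelial libraries without replicates 1 and 3, the cause was not tested.

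Of the named genes, 2 changed sign, both with library size alone, Top2a in erythroid against endothelial libraries (log2 difference −0.17) and Birc5 in double positive against endothelial libraries (−0.005175). Of 66 list tests, 34 lost their call with an estimated correlation and 32 kept their direction and side of the threshold. With library size alone the direction of camera turned for hemogenic (adjusted p = 0.859), megakaryocyte (0.883) and mesenchyme (0.809) genes in erythroid against endothelial libraries, and for pan-hematopoietic (0.708) and macrophage (0.906) genes in double positive against erythroid libraries. With fry 51 list tests kept their direction and side of the threshold and 10 gained a call. The direction turned with fry for visceral endoderm genes in erythroid against endothelial (adjusted p = 0.0153), glycolysis in double positive against endothelial (0.256), and hemogenic (0.023), iron handling (0.379) and megakaryocyte (0.0323) genes in double positive against erythroid libraries. The cause was not tested for these. In simulated data with only 50 of 12136 genes changed at each fold, 8%, 0% and 0% of 2-fold changes were recovered. The real comparisons called many more genes, which makes their adjusted threshold less strict. These rates therefore do not give the share of 2-fold changes missed in the real comparisons.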

Other observations

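The tests of a common erythroid share, a common endothelial share, transcript abundance, visceral endoderm, chance overlap and chance differences in the visceral endoderm list, and the gene sets in the last paragraph, were chosen after the result was seen.

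The comparison of erythroid with endothelial libraries called 4977 genes, and the highest count in another split of the 6 libraries into 3 and 3 was 0. Of the 10 splits, 1 gave as many genes, the real one, and 10 splits are too few for a share under 0.05.

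The double positive libraries held both endothelial and erythroid transcripts. Libraries simulated as mixtures of the 2 other populations had at most 5 genes above both, against 1132 observed, and visceral endoderm genes summed to 104100 CPM against 48.7 and 22.0 CPM in those populations, which argues against their being the sole contents of the gate, while a mixture that also holds another cell type stays open. Erythroid RNA at 1 common share is argued against by 38 erythroid genes, whose log2 ratios of double positive to erythroid level spread 2.28 times their median standard error, although a share from erythroid cells of another maturity, or with some genes added by another cell type, stays open. Transcript abundance had a Spearman correlation of 0.206 with that ratio across genes, which are not independent replicates. For 35 endothelial genes the spread was 1.64 times the standard error, so that a common share of endothelial cells and lower expression in each cell cannot be told apart.

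Erythroid transcripts were present at low level in the endothelial libraries. Free RNA or cells of the erythroid population would bring them in the proportions of the erythroid libraries, but the highest correlation of log2 CPM across 69 erythroid-list genes was 0.125 over the 3 libraries. The correlation bears only on the main source of these transcripts. Globin traces stood at 0.00134% to 0.00252% of the erythroid level, and carry-over at that share would add too little to most of these genes to move it. Such carry-over stays open. No biological explanation was tested.

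Genes above both other populations included 100% of the tested visceral endoderm list, which was fixed before the data were examined and shares no gene with another list. RNA or cells of visceral endoderm in the double positive libraries are a candidate explanation, with Afp at 54340 CPM and Rbp4 at 5806 CPM. Whether the gate on VE-Cadherin and GFP removed such cells was not tested. Expression of these genes by the double positive cells themselves stays open, since a pool does not show which cell held a transcript. The list gives 25 of the 1132 genes above both. Of 9 mesenchyme and mesothelium genes 7 were also above both, that list summing to 449 CPM against 21.6 CPM in endothelial and 0.264 CPM in erythroid libraries. Their source was not tested. For the visceral endoderm list, the smallest gap in score between a double positive library and any other was 20.7 times the largest range within a population. That argues against chance differences of the size seen between these pools. The range may be technical, so the test cannot speak to chance between embryos or sorts. For the other genes above both, the part owed to chance overlap of comparisons that share the double positive libraries stays open, since the 20 sets of unchanged simulated libraries, with at most 0 genes above both, held too few calls to overlap as much.

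Gene sets chosen after their values were seen were tested with camera, adjusted over 12 tests. Because the same values led to the choice of these sets, their p-values are descriptive and do not measure chance. Of 24 imprinted genes 17 were lower in erythroid than endothelial libraries (adjusted p = 2.84e-06, and 0.0422 with an estimated correlation), and 20 were higher in double positive than erythroid libraries (adjusted p = 2.84e-06, and 0.0422 with an estimated correlation). Between double positive and endothelial libraries 6 were higher and 5 lower (adjusted p = 0.823). Of 77 respiratory chain genes 69 were higher in double positive than endothelial libraries (median log2 difference 1.25, and 0.61 under library size alone; adjusted p = 2.5e-15; adjusted p = 0.162 with an estimated correlation). Of the same 77 genes, 55 were higher in erythroid than endothelial libraries, with a median of 0.81 that was −0.74 under library size alone (adjusted p = 9.96e-15; adjusted p = 0.162 with an estimated correlation), and 31 were higher and 3 lower in double positive than erythroid libraries (adjusted p = 0.823). Of 17 proton pump (V-ATPase) genes 11 were above both populations (adjusted p = 0.0016 against endothelial and 0.0321 against erythroid libraries; adjusted p = 0.162 and 0.259 with an estimated correlation), and 2 were higher and 4 lower in erythroid than endothelial libraries (adjusted p = 0.62). Of 11 cathepsin genes 1 was higher and 7 lower in erythroid than endothelial libraries (adjusted p = 0.0171; adjusted p = 0.172 with an estimated correlation), 4 higher and 3 lower in double positive than endothelial (adjusted p = 0.823), and 6 higher and 2 lower in double positive than erythroid libraries (adjusted p = 0.105).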
